A study of Mus musculus with 8 samples.

How the data were processed

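Germinal centre B cells from mice carrying 1 S74C allele of RagC (gene Rragc) and from wild-type mice were profiled by RNA sequencing, with 4 libraries per genotype and 8 libraries in all. Per the labels, the germinal centre response was induced with SRBC (sheep red blood cells), and the cells were sorted as CD19-positive, CD95-positive and CD38-negative. Per the labels' protocols, RNA integrity numbers averaged 9.75 (range 9 to 10), polyA RNA was taken from 1 µg of total RNA, and libraries were made with a strand-preserving kit. All 8 libraries were labelled with the same lane, lane 6.

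The deposited values are FPKM, fragment counts scaled by transcript length and by the mapped fragments of the library, with 1 value per gene and library, in 1 table made by the authors. Per the submitters' processing notes, FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks were used, and the builds GRCh38 and mm10 are both listed, without a role for either. The normalization between libraries, the annotation and the use of strand in the quantification are not given in the sources used here. The table held 23951 genes by symbol, and each of its columns of values was matched to a library by title. FPKM are not counts and the number of fragments per library is not given, so depth is unknown and no interval that needs it is printed. Total FPKM per library ran from 871194 to 1148002. Low values showed only partial steps of single reads, and whole reads were not recovered from them. Division by transcript length and total makes each value depend on the gene model used and on the most abundant genes of the library.

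Genotype was taken from the genotype label of each sample. Replicate numbers follow the order of the samples and pair nothing. The labels give 4 mice per genotype and do not say in so many words that each library is 1 mouse, so p-values measure the spread between these libraries. No pair of libraries held identical values. Library titles fall into 3 runs of consecutive numbers, and the labels do not say what the runs mean.

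Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested, which left 9925. Values were analysed as log2(FPKM + 1), so a fold change understates the change of a gene with low FPKM. The 2 genotypes were compared with limma 3.58.1 in R 4.3.3, with a variance trend and two-sided tests, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are S74C/+ minus wild type with the standard error (SE) of the fit. Levels are means of FPKM with the standard deviation (SD) of 4 libraries. For single genes, and for the mean log2 level of each gene list, an exact two-sided permutation test over the 70 assignments was also run. Its smallest possible p is 0.0286.

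Before the data were examined, 28 gene lists were fixed from textbook knowledge of germinal centre B cells, of the Rag and mTORC1 pathway and of other cell types a sorted sample could hold. Lists with at least 5 tested members were compared with all other genes by camera of limma, with a preset correlation of 0.01 between genes and adjustment over the 27 lists tested. The alternatives were camera with a correlation estimated from the data, camera on ranks, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes. The genes named here were set by a rule fixed at the same time. It took Rragc, the genes of the sort gate, up to 12 genes per direction past the threshold without overlap between genotypes, filled to 6 by smallest p where fewer passed, and the 2 to 4 members of each list with the smallest p. Predicted genes without a name and receptor segments were not named.

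Gene positions, GC content and transcript length came from GENCODE M21 (GRCm38, the same assembly as mm10). Of the genes in the table, 22658 matched by symbol and 925 by an older symbol, and 99.3% of the genes tested had a GC value. The GC and length correction subtracted from each library a spline, with 4 degrees of freedom per property, of the deviation of each gene from its mean.

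The steps were tested on simulated data for the comparison of S74C/+ with wild type, with 9925 genes at their measured means and spreads, 200 of them changed, in 10 simulations. Of the genes changed by 0.5 on the log2 scale 14.0% were recovered, of those changed by 1 84.2%, and of those changed by 2 98.9%, and 4.4% of calls were false. With 0 genes changed there were 0.0 false calls per simulation without library weights and 0.1 with them. With the noise of 1 wild-type library doubled, 4.0%, 67.9% and 95.5% of genes changed by 0.5, 1 and 2 were recovered without library weights, and 10.7%, 79.0% and 98.6% with them. Of the calls in these runs, 2.3% were false without weights and 4.6% with them. The noise was independent between genes, so false calls under a trend shared by many genes were not measured. A list shifted by 0.25 was called in 10 of 10 simulations, and 5 of 260 unchanged lists were called, with genes simulated as independent. A GC trend put into 1 library gave a rho of 0.73 with GC before the correction and 0.01 after it.

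Alternatives fixed with the lists were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, the same total in each library, median centring, quantile normalization, no variance trend, robust moderation, library weights, no receptor segments, the runs of titles as a block, the Xist level as a covariate if it split the libraries, an adjusted p of 0.1 and each library left out. Added after seeing the data were the GC correction, the GC and length correction, that correction with the title-run block, the fit without the libraries of the last title run, and the fit without S74C/+ replicates 2 and 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.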

Results

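The libraries compare germinal centre B cells of mice heterozygous for S74C in RagC (S74C/+) with those of wild-type mice. RagC is a small GTPase that pairs with RagA or RagB and recruits the growth kinase complex mTORC1 to lysosomes when amino acids are present. Germinal centre B cells are the activated B cells that mutate and select their antibody genes after immunisation. Gene expression was measured as FPKM in 4 S74C/+ and 4 wild-type libraries, whose total FPKM ran from 871194 to 1148002 and whose depth in reads is unknown. Log2 values of any 2 libraries correlated across genes, which are not independent replicates, with r between 0.927 and 0.981. Replicate 4 of each genotype, the 2 libraries of the last title run, stood apart. Their scores on the first principal component, which held 35.8% of the variance, were 48.1 for wild type and 18.2 for S74C/+, and those of the other libraries lay between -29.1 and 1.2. In both, the deviation of genes from their means followed GC content across genes, with a rho of 0.504 in wild-type replicate 4 and 0.607 in S74C/+ replicate 4, against -0.586 in wild-type replicate 1.

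**Figure D1:**
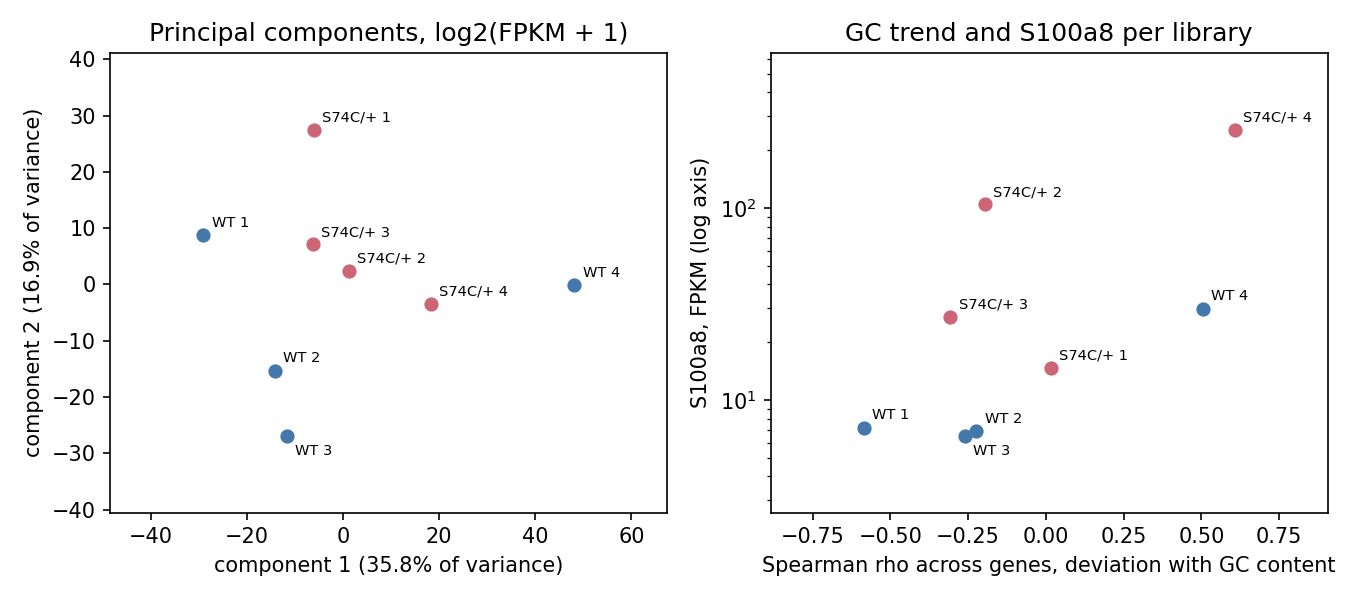
Left, the 8 libraries by their scores on the first 2 principal components of log2(FPKM + 1). Right, the Spearman rho of each library with GC content across genes, against the FPKM of S100a8 on a log axis. Each point is 1 library, coloured by genotype, and wild-type replicate 4 lies farthest from the others on the first component, at 48.1.

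The main question of the design is which genes differ between S74C/+ and wild-type germinal centre B cells. Fscn1 and Emp2 rose in S74C/+. Fscn1 encodes fascin, which bundles actin filaments, and its level was 6.58 ± 0.544 FPKM in wild type and 16.0 ± 1.14 FPKM in S74C/+ (SD, n = 4), a log2 fold change of 1.17 (SE 0.117, limma adjusted p = 0.0155). Emp2 encodes a membrane protein of the tetraspan family, and its level was 1.93 ± 0.360 FPKM in wild type and 5.68 ± 0.440 FPKM in S74C/+ (SD, n = 4), a log2 fold change of 1.20 (SE 0.135, limma adjusted p = 0.0233). Both were higher in all 4 S74C/+ libraries than in any wild-type library. Fscn1 lies on chromosome 5 at 142960343 to 142973185 and Emp2 on chromosome 16 at 10281749 to 10313968 (GRCm38). With limma, 2 of the 9925 genes tested were higher and 0 were lower at an adjusted p of 0.05. At an unadjusted p of 0.05, 226 were higher and 182 lower, 408 in all where 496 are expected with no effect. This count was 2023 without wild-type replicate 4, 1995 with library weights, 1634 without the last title run and 730 with the title-run block. Values did not overlap between genotypes for 151 genes higher and 135 genes lower in S74C/+, 2.88% of genes where chance gives 2.86%.

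Fscn1 and Emp2 were higher in S74C/+ under every alternative that tested them, with log2 fold changes of 1.07 to 1.27 for Fscn1 and 1.11 to 1.52 for Emp2. Their adjusted p ran from 5.05e-04 to 0.352 and from 5.05e-04 to 0.528. The count of genes depended on single libraries. Without wild-type replicate 4, 18 genes were higher and 8 lower, Fscn1 and Emp2 among those higher. Without wild-type replicate 1, or without S74C/+ replicate 1, 3 or 4, 0 passed limma in either direction, with 503, 289, 329 and 358 genes at an unadjusted p under 0.05. Mir142b, Snord55 and Cdkn2a, named next, were chosen after their values were seen. Without wild-type replicate 2 the 1 gene past the threshold was Mir142b, without wild-type replicate 3 the 2 genes were Fscn1 and Hist4h4, and without S74C/+ replicate 2 the 1 gene, lower, was Snord55. The log2 fold changes were 6.12 for Mir142b and -8.09 for Snord55, and neither passed in any fit of all 8 libraries. With the title-run block the 2 genes were Fscn1 and S100a9. Without the last title run 11 genes were higher, with Fscn1 and Emp2, and Cdkn2a was lower, and without S74C/+ replicates 2 and 4 Snord55 was lower. With library weights, which gave wild-type replicate 4 a weight of 0.146 and the others 0.661 to 2.73, 63 genes were higher and 58 lower. After the GC correction, and with the same total in each library, 0 passed, with 618 and 341 genes at an unadjusted p under 0.05.

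Next by p among genes without overlap, and not past the threshold with an adjusted p of 0.284 each, were 4 genes at higher and 6 at lower levels in S74C/+. Cd3g, a chain of the T cell receptor complex, was at 1.89 ± 0.788 FPKM in wild type and 4.68 ± 0.610 FPKM in S74C/+ (SD, n = 4). Rsph1, of the radial spokes of cilia, was at 6.78 ± 1.75 and 13.9 ± 0.929 FPKM, and S100a11, a calcium-binding protein, at 138.1 ± 11.1 and 214.2 ± 28.2 FPKM. Hist4h4 was at 3.46 ± 1.71 and 9.34 ± 0.720 FPKM, and its value is uncertain, since FPKM cannot show whether fragments of related histone H4 genes enter it. On the lower side, S1pr1, the receptor that draws lymphocytes out towards blood and lymph, was at 4.39 ± 0.492 FPKM in wild type and 2.19 ± 0.129 FPKM in S74C/+. The transcriptional repressor Bhlhe40 was at 3.93 ± 1.04 and 1.75 ± 0.202 FPKM, and the repressor Gfi1 at 1.76 ± 0.183 and 0.644 ± 0.216 FPKM. Fam167a was at 1.22 ± 0.191 and 0.326 ± 0.0782 FPKM. Xylt1, which starts glycosaminoglycan chains, was at 1.79 ± 0.292 and 0.679 ± 0.150 FPKM, and Myof, a membrane repair protein, at 1.68 ± 0.177 and 0.717 ± 0.0914 FPKM. With library weights all 12 of these genes, Fscn1 and Emp2 included, passed the threshold, and without wild-type replicate 4 5 of them did. The 12 were chosen by p and lack of overlap in the same libraries, so these fits are no separate support.

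**Figure D2:**
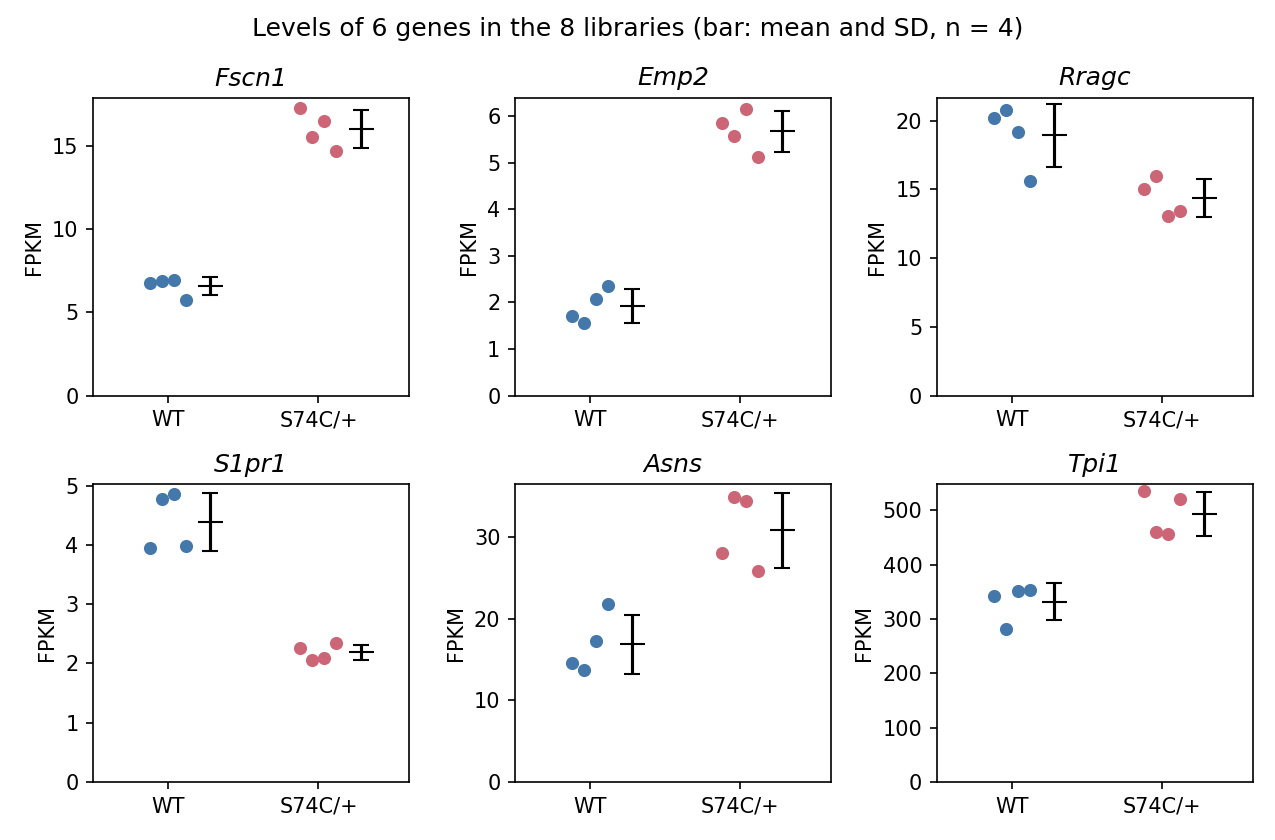
FPKM of 6 genes in each of the 4 wild-type and 4 S74C/+ libraries (points), with the mean and SD beside them. Fscn1 and Emp2 passed the threshold over all genes, with means of 16.0 and 5.68 FPKM in S74C/+, and Rragc, S1pr1, Asns and Tpi1 did not.

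Rragc itself was at 18.9 ± 2.30 FPKM in wild type and 14.4 ± 1.35 FPKM in S74C/+ (SD, n = 4), a log2 fold change of -0.37 (SE 0.129). The difference did not pass the adjustment (limma adjusted p = 0.998) or the exact permutation test (p = 0.0571), and wild-type replicate 4, at 15.6 FPKM, lay within the S74C/+ range. The gene lies on chromosome 4 at 123917446 to 123936997 (GRCm38). FPKM of the whole gene cannot tell the alleles apart. Of the genes of the sort gate, Cd19 was at 516.9 ± 138 and 527.1 ± 47.0 FPKM and Fas, which encodes CD95, at 80.9 ± 14.9 and 87.1 ± 12.4 FPKM in wild type and S74C/+. Cd38 was at 7.49 ± 3.44 and 4.64 ± 0.836 FPKM, with 2.38 FPKM in wild-type replicate 4. The adjusted p of all 3 was 0.998. Without wild-type replicate 4 Cd38 passed the threshold as lower, with a log2 fold change of -0.87 where it was -0.47 with all libraries (adjusted p = 0.0494, range 0.0494 to 0.9999). The fixed list of Rag, Ragulator, GATOR and mTORC1 genes did not pass (camera adjusted p = 0.162), with 18 of 39 members higher, 21 lower and 0 past the threshold adjusted over the list alone. Its members Eif4ebp1, a translation repressor that mTORC1 phosphorylates, and Tsc1, an inhibitor of mTORC1, were at 34.3 ± 2.93 and 41.6 ± 4.17 FPKM and at 4.75 ± 0.562 and 3.82 ± 0.244 FPKM in wild type and S74C/+.

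Of 27 fixed lists, 14 passed camera with the preset correlation, 10 of them higher and 4 lower in S74C/+. With an estimated correlation 0 passed, the smallest adjusted p being 0.241 and 4 lists having an unadjusted p under 0.05, and fry called 0, with 5 at an unadjusted p under 0.05. Without wild-type replicate 1, or without S74C/+ replicates 2 and 4, 9 lists passed with the preset correlation, and without wild-type replicate 4 19 did. Adjusted over all genes tested, 0 of the 762 tested members of the lists passed limma, with 34 higher and 15 lower at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of the 13 lists that did not pass camera did, with 12 at an unadjusted p under 0.05. Ranges of adjusted p given below are over the alternatives that use camera without an estimated correlation, 26 for most lists and 25 for the T cell, NK cell and stromal lists.

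Genes of glycolysis and targets of the hypoxia factor HIF1 were the list of highest median after the blood cell markers below, at 0.25 on the log2 scale, with 22 of 28 members higher in S74C/+ (camera adjusted p = 5.39e-09, and adjusted p = 0.241 with an estimated correlation). Adjusted over the list alone, 1 member passed, Tpi1, the triose phosphate isomerase of glycolysis, at 331.9 ± 33.8 FPKM in wild type and 493.5 ± 41.0 FPKM in S74C/+ (SD, n = 4). The HIF1 targets Bnip3 and Ankrd37 were at 3.05 ± 1.29 and 5.88 ± 0.117 FPKM and at 16.1 ± 3.27 and 27.3 ± 7.19 FPKM, and the aldolase Aldoc at 5.62 ± 0.860 and 9.05 ± 2.24 FPKM. The 6 members lower, named here after their values were seen, were Hif1a itself, Kdm3a, Pfkfb3, Ero1l, Slc2a3 and Slc16a1. Their log2 fold changes ran from -0.115 to -0.015, so the rise was not shared by every member. Targets of MYC and genes of ribosome biogenesis had a median of 0.13, with 48 of 55 members higher (camera adjusted p = 4.17e-07, and adjusted p = 0.241 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Of these, the mitochondrial chaperonin genes Hspe1 and Hspd1 were at 221.4 ± 17.4 and 270.9 ± 25.5 FPKM and at 73.2 ± 4.99 and 90.1 ± 11.3 FPKM, and the spermidine synthase Srm at 62.2 ± 9.92 and 79.0 ± 8.94 FPKM. Neither list lost its call when any 1 library was left out.

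Genes of cytosolic ribosomal proteins had a median of 0.15, with 76 of 78 members higher (camera adjusted p = 5.39e-09, and adjusted p = 0.538 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Rpl37a was at 6033 ± 867.9 FPKM in wild type and 7540 ± 1356 FPKM in S74C/+, and Rps4x at 3980 ± 403 and 4608 ± 411.9 FPKM (SD, n = 4). Quantile normalization ended the call and brought the median to -0.0001 (adjusted p = 0.824, range 4.81e-14 to 0.824), and the GC and length correction brought it to 0.07, with the list still past the threshold (adjusted p = 0.00176). Nuclear genes of oxidative phosphorylation had a median of 0.09, with 67 of 76 members higher (camera adjusted p = 1.10e-05, and adjusted p = 0.565 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Ndufs7 and Ndufb3, subunits of complex I, were at 233.3 ± 22.7 and 281.3 ± 37.5 FPKM and at 132.1 ± 17.5 and 153.9 ± 9.70 FPKM. The call ended with quantile normalization (adjusted p = 0.0977), the GC and length correction (adjusted p = 0.133) and without the last title run (adjusted p = 0.0801), over a range of 1.41e-08 to 0.133. With the same total in each library the median of all genes shifted to -0.10, and that of the oxidative phosphorylation list to -0.02, still above the shift. The medians of the glycolysis, MYC target and ribosomal protein lists fell to 0.145, 0.044 and 0.041, and that of the ATF4 list below to 0.0098. The size of each median therefore depends on this scaling.

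Targets of ATF4, the factor induced by amino acid shortage, and genes of amino acid supply had a median of 0.11, with 27 of 36 members higher (camera adjusted p = 0.00133, and adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 1 member passed, the asparagine synthetase Asns, at 16.9 ± 3.63 FPKM in wild type and 30.8 ± 4.56 FPKM in S74C/+ (SD, n = 4). Without wild-type replicate 4 Asns also passed over all genes (adjusted p = 0.0398, range 0.00574 to 0.9997). The seryl-tRNA synthetase Sars was at 54.3 ± 8.26 and 65.4 ± 3.25 FPKM, and Psph, the last enzyme of serine synthesis, at 26.2 ± 2.34 and 30.5 ± 1.34 FPKM. The 9 members lower, named here after their values were seen, were Slc38a1, Slc38a2, Slc7a1, Slc1a5, Trib3, Cth, Sesn2, Cebpg and Ddit3. Their log2 fold changes ran from -0.28 to -0.0021, so the rise was not shared by the whole list. Without wild-type replicate 1 the list missed the threshold (adjusted p = 0.0842, range 1.67e-04 to 0.0842). TFEB targets and genes of lysosome and autophagy had a median of -0.10, with 35 of 46 members lower (camera adjusted p = 8.75e-04, and adjusted p = 0.498 with an estimated correlation) and 0 past the threshold adjusted over the list alone. The lysosomal enzymes Gns and Hexa were at 18.2 ± 2.36 and 13.3 ± 1.40 FPKM and at 30.4 ± 7.34 and 21.4 ± 1.93 FPKM, and Gabarapl1, of autophagosome membranes, at 2.06 ± 0.233 and 1.32 ± 0.294 FPKM. Without wild-type replicate 3 the list missed the threshold (adjusted p = 0.0805, range 1.23e-06 to 0.0805). The sterol and fatty acid synthesis list did not pass (camera adjusted p = 0.162), with 20 of 32 members lower, and did without wild-type replicate 4, where its mean level was lowest (adjusted p = 0.00514), with library weights (8.18e-04) and without the last title run (0.00141, range 8.18e-04 to 0.584). Fads2, a fatty acid desaturase, was at 12.1 ± 2.01 and 9.78 ± 0.590 FPKM and the LDL receptor gene Ldlr at 6.53 ± 1.46 and 5.06 ± 1.14 FPKM.

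**Figure D3:**
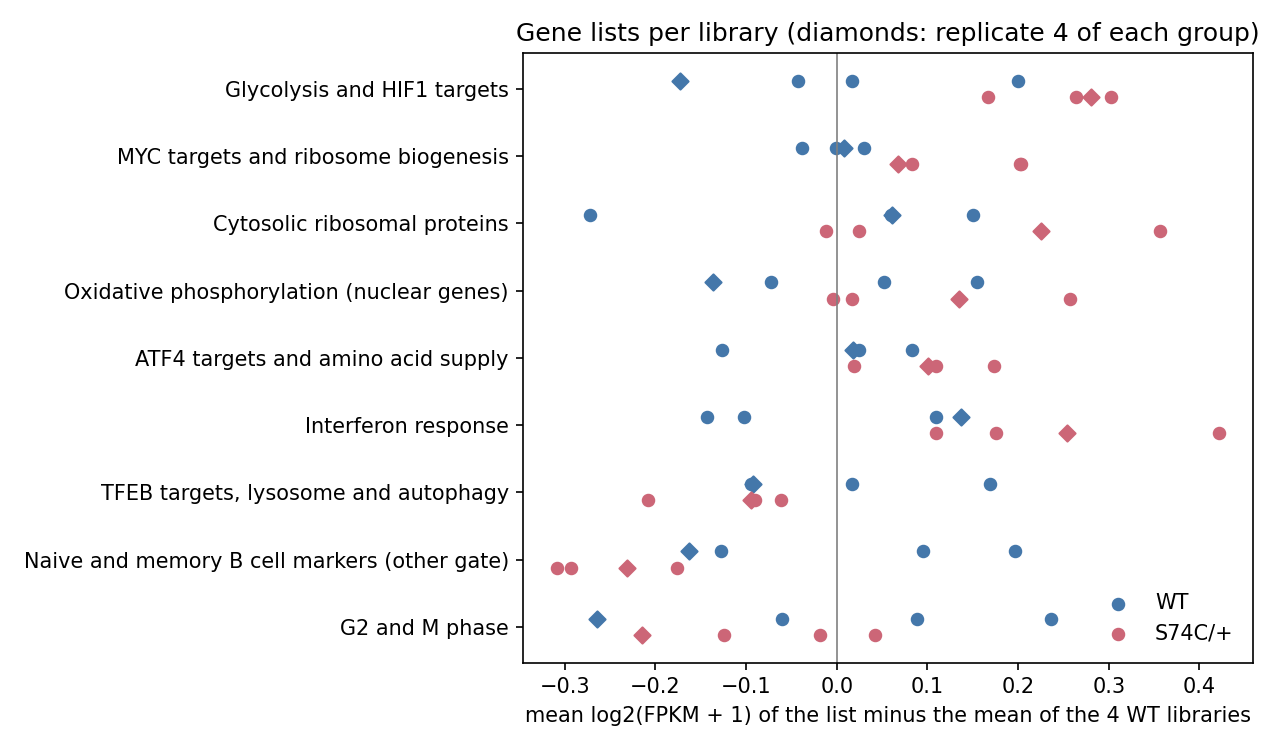
Mean log2(FPKM + 1) of the tested members of 9 lists in each library, minus the mean of the 4 wild-type libraries. Points are libraries coloured by genotype, with replicate 4 of each genotype as a diamond. The mean difference of S74C/+ from wild type was 0.25 for the glycolysis list and -0.25 for the naive and memory B cell list.

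Interferon response genes had a median of 0.17, with 20 of 26 members higher in S74C/+ (camera adjusted p = 5.80e-06, and adjusted p = 0.326 with an estimated correlation). Adjusted over the list alone, 2 members passed, the ubiquitin-like modifier Isg15, at 6.99 ± 1.61 FPKM in wild type and 15.4 ± 5.09 FPKM in S74C/+, and the GTPase Igtp, at 4.65 ± 0.220 and 7.01 ± 0.558 FPKM (SD, n = 4). Ifi27l2a was at 328.8 ± 90.9 and 507.4 ± 81.4 FPKM and Bst2, which tethers virus particles, at 21.6 ± 5.38 and 29.8 ± 3.41 FPKM. Isg15 was highest in S74C/+ replicates 2 and 4, at 21.8 and 17.1 FPKM against 10.5 and 12.3 FPKM in replicates 1 and 3. The mean log2 level of the whole list was also highest in replicates 2 and 4. It was 3.307, 3.553, 3.241 and 3.385 in S74C/+ replicates 1 to 4. The other members named here did not share this order. In S74C/+ replicates 1 to 4, Igtp was at 7.35, 7.59, 6.38 and 6.73 FPKM and Bst2 at 32.68, 32.85, 27.1 and 26.65 FPKM. Ifi27l2a was at 534.9, 511.1, 395.2 and 588.2 FPKM. These 2 libraries, replicates 2 and 4, also had the most S100a8, a neutrophil transcript, at 104.4 and 256.1 FPKM. Without them the log2 fold change of Isg15 was 0.65, where it was 1.01 with all libraries, and the list had a camera adjusted p of 0.0185 (range 7.78e-08 to 0.0185).

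Markers of naive and memory B cells, which the CD38-negative gate is meant to leave out, had a median of -0.21, with 18 of 21 members lower in S74C/+ (camera adjusted p = 1.43e-05, and adjusted p = 0.326 with an estimated correlation). Adjusted over the list alone, 2 members passed, S1pr1, with the values above, and the chemokine receptor Ccr7, at 4.20 ± 1.32 FPKM in wild type and 2.03 ± 0.418 FPKM in S74C/+ (SD, n = 4). The chemokine receptor Ccr6 was at 4.77 ± 2.36 and 2.13 ± 0.394 FPKM, and Zbtb32, a repressor, at 5.30 ± 0.158 and 7.51 ± 2.04 FPKM, in the other direction. Neither the interferon list nor this one lost its call when any 1 library was left out.

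Germinal centre identity genes did not pass (camera adjusted p = 0.671), with 26 of 39 members lower. Bach2, which holds back plasma cell formation, was at 19.2 ± 4.05 FPKM in wild type and 13.6 ± 1.41 FPKM in S74C/+, the confinement receptor S1pr2 at 159.9 ± 15.5 and 136.0 ± 5.51 FPKM, and Efnb1 at 33.9 ± 4.86 and 27.5 ± 2.60 FPKM (SD, n = 4). Mef2b went the other way, at 436.6 ± 168.9 and 539 ± 36.5 FPKM. Without wild-type replicate 4 Mef2b passed over all genes as higher (limma adjusted p = 0.0473). With library weights Mef2b passed as higher (limma adjusted p = 0.0431) and Bach2 as lower (0.0318). The dark zone list did not pass (camera adjusted p = 0.158), with 10 of 12 members lower, and did without wild-type replicate 4 (adjusted p = 0.00649), with library weights (0.00821) and without the last title run (0.00884, range 0.00649 to 0.505). Its member Foxo1 was at 25.6 ± 3.12 and 22.9 ± 0.899 FPKM. The light zone, CD40, NF-kB and B cell receptor list did not pass (camera adjusted p = 0.9750), with 19 of 42 members higher, and passed as higher without wild-type replicate 4 (adjusted p = 0.0210) and without the last title run (0.00570, range 0.00570 to 0.999). It held the cyclin gene Ccnd2 at 2.44 ± 0.227 and 3.48 ± 0.593 FPKM and Egr3 at 2.47 ± 0.814 and 1.49 ± 0.310 FPKM. S phase genes did not pass (camera adjusted p = 0.946), with 19 of 38 members higher, Chaf1b at 52.96 ± 6.24 and 59.2 ± 4.13 FPKM and Pole at 17.5 ± 3.89 and 15.1 ± 0.952 FPKM. G2 and M phase genes had a median of -0.09, with 30 of 40 members lower (camera adjusted p = 0.0373, and adjusted p = 0.719 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Gtse1 was at 18.5 ± 2.44 and 15.4 ± 0.512 FPKM and Foxm1, a factor of mitotic genes, at 26.0 ± 4.64 and 21.9 ± 2.01 FPKM. This call ended with the title-run block (adjusted p = 0.399) and with the block and the GC and length correction (0.503). It also ended without wild-type replicate 1 (0.942), wild-type replicate 2 (0.159), S74C/+ replicate 2 (0.176) or S74C/+ replicate 4 (0.311), and with the GC correction (0.0672), the GC and length correction (0.0721) or median centring (0.0518). Without S74C/+ replicates 2 and 4 its direction turned (adjusted p = 0.982), over a range of 0.00185 to 0.982.

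The plasma cell list had a median of -0.14, with 17 of 23 members lower (camera adjusted p = 0.0197, and adjusted p = 0.702 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Chst1 was at 2.11 ± 0.941 FPKM in wild type and 0.991 ± 0.459 FPKM in S74C/+, Slamf7 at 31.2 ± 5.06 and 24.0 ± 3.85 FPKM, and Slpi, a protease inhibitor, at 428.7 ± 161.7 and 677.8 ± 143.8 FPKM, in the other direction (SD, n = 4). The call ended without wild-type replicate 1 (adjusted p = 0.534), wild-type replicate 3 (0.107), S74C/+ replicate 3 (0.149) or S74C/+ replicate 4 (0.222), with library weights (0.457), without the last title run (0.103) and without S74C/+ replicates 2 and 4 (0.261), over a range of 3.83e-05 to 0.534. Unfolded protein response genes did not pass (camera adjusted p = 0.139), with 15 of 23 members lower, and did without wild-type replicate 2 (adjusted p = 0.0295) or S74C/+ replicate 2 (0.00885), with quantile normalization (0.0449) and with the title-run block (0.0437), over a range of 0.00885 to 0.877. It held the chaperone Dnajb9 at 7.43 ± 1.31 and 4.66 ± 1.29 FPKM and Sel1l at 11.2 ± 0.360 and 9.12 ± 0.594 FPKM. The BCL2 family and apoptosis list did not pass (camera adjusted p = 0.903), with 12 of 25 members higher, Diablo at 24.6 ± 3.48 and 30.1 ± 1.601 FPKM and Bcl2a1d at 6.15 ± 0.971 and 8.07 ± 1.40 FPKM. The p53 target list did not pass (camera adjusted p = 0.418), with 12 of 19 members lower, Plk2 at 3.67 ± 1.12 and 2.28 ± 0.426 FPKM and Trp53inp1 at 13.5 ± 6.27 and 7.87 ± 0.798 FPKM. Trp53inp1 passed over all genes without wild-type replicate 4 (adjusted p = 0.0473, range 0.0447 to 0.9999). The class switching list, of which 6 of 18 genes were in the table and no immunoglobulin constant gene, did not pass (camera adjusted p = 0.985), with Il4ra at 60.1 ± 13.6 and 50.8 ± 5.88 FPKM and Batf at 40.5 ± 14.4 and 46.6 ± 4.19 FPKM. Early response and dissociation stress genes did not pass (camera adjusted p = 0.175), with 16 of 26 members higher, and did without wild-type replicate 4 (adjusted p = 0.0327, range 0.0327 to 0.769). Of these, Hsp90aa1 was at 195.1 ± 14.2 and 261.3 ± 27.3 FPKM, and Hspe1 had the values above.

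Markers of other cell types that the gate is meant to remove were present in some libraries. Neutrophil markers had a median of 0.85, with 11 of 11 members higher in S74C/+ (camera adjusted p = 4.26e-06, and adjusted p = 0.354 with an estimated correlation), and erythroid markers a median of 0.89, with 11 of 13 higher (camera adjusted p = 7.71e-05, and adjusted p = 0.354 with an estimated correlation). For both, 0 members passed adjusted over the list alone. S100a8, an abundant neutrophil transcript, was at 256.1 FPKM in S74C/+ replicate 4, 104.4 in S74C/+ replicate 2, 27.2 in S74C/+ replicate 3, 14.7 in S74C/+ replicate 1 and 29.9 in wild-type replicate 4, and between 6.50 and 7.18 in the other wild-type libraries. S100a9 was at 12.4 ± 15.9 FPKM in wild type and 72.5 ± 81.3 FPKM in S74C/+ (SD, n = 4). The haemoglobin gene Hba-a1, named here after its values were seen, ranged from 34.9 to 470 FPKM in wild type and from 113.8 to 1512 FPKM in S74C/+, and the carbonic anhydrases Car1 and Car2 of red cells were at 0.403 ± 0.4998 and 1.97 ± 1.21 FPKM and at 2.70 ± 0.860 and 8.66 ± 6.51 FPKM. Without S74C/+ replicates 2 and 4, left out because they had the most neutrophil RNA, the log2 fold changes of S100a8 and S100a9 were 0.93 and 1.28, where they were 2.41 and 2.46 with all libraries. Neither list passed in that fit (adjusted p = 0.341 for neutrophil and 0.239 for erythroid markers), the highest of ranges that begin at 4.82e-12 and 1.24e-13. The libraries were chosen by the level of the neutrophil list. The fall of S100a8 and S100a9 and the lost neutrophil call therefore follow from that choice and test no cause.

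T cell markers had a median of 0.14, with 11 of 13 members higher (camera adjusted p = 0.00727, and adjusted p = 0.354 with an estimated correlation). Cd3g, with the values above, was the 1 member past the threshold adjusted over the list alone, and Zap70 was at 1.38 ± 1.10 FPKM in wild type and 2.83 ± 1.35 FPKM in S74C/+ (SD, n = 4). Cd3e, another chain of the complex of Cd3g and named here after its values were seen, did not rise with it. It ranged from 0.91 to 1.87 FPKM in wild type and from 0.446 to 1.25 FPKM in S74C/+. The call ended without wild-type replicate 1 (adjusted p = 0.0690), wild-type replicate 2 (0.0738) or S74C/+ replicate 4 (0.0729), and without S74C/+ replicates 2 and 4 together (0.356). It also ended with no filter (0.111), the GC and length correction (0.0634) and that correction with the title-run block (0.0613), over a range of 2.02e-04 to 0.356. The median of 0.14 was the same after the GC and length correction. NK cell markers, of which 5 were tested and 3 were higher, had a median of 0.18 (camera adjusted p = 0.0368, and adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 1 member passed, Il2rb, a chain of the interleukin receptors, at 2.39 ± 0.854 and 4.22 ± 0.214 FPKM, and the transcription factor gene Tbx21 was at 9.04 ± 3.64 and 14.1 ± 3.14 FPKM. This call ended without any 1 of wild-type replicates 1, 2 and 3 and S74C/+ replicates 2 and 4, at adjusted p between 0.0585 and 0.179, and held in 11 of 25 alternatives. It also ended with a pseudocount of 0.1 (0.0504), no filter (0.999), median centring (0.0550), the GC correction (0.0877), the GC and length correction (0.143), that correction with the title-run block (0.152) and ranks (0.155). After the GC and length correction the median of the NK cell list was still 0.15. Without the last title run the adjusted p of this list was 0.0603 and without S74C/+ replicates 2 and 4 0.575, over a range of 0.00240 to 0.999. Macrophage and dendritic cell markers did not pass (camera adjusted p = 0.838), with 8 of 15 members higher, and passed as higher without wild-type replicate 4 (adjusted p = 0.0210) and with library weights (0.0303), and as lower without S74C/+ replicates 2 and 4 (adjusted p = 2.14e-05), over a range of 2.14e-05 to 0.994. Of these, Csf2rb was at 2.40 ± 0.618 and 1.38 ± 0.227 FPKM and Vcam1 at 2.62 ± 2.07 and 1.53 ± 0.684 FPKM. Stromal and endothelial markers did not pass (camera adjusted p = 0.406), with 8 of 9 members lower, and did without wild-type replicate 2 (adjusted p = 0.0442, range 0.0442 to 0.980). Of these, Egfl7 was at 1.17 ± 0.407 and 1.43 ± 0.211 FPKM and Col1a2 at 1.33 ± 0.605 and 1.01 ± 0.196 FPKM. The list of sex-linked genes had 4 tested members and was not tested. For the macrophage list the median was 0.05 and the mean -0.02, and for the light zone, S phase and apoptosis lists the median, the mean and the direction of the test also differed in sign.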

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

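Among 228 groups of 4 values examined for a library far from the other 3, 14 were picked out where chance alone gives about 11, or 1 in 20. Of the tests below, those of the GC and length correction and of the neutrophil and erythroid genes were chosen after the results were seen, as were the fits without the last title run and without S74C/+ replicates 2 and 4.

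Wild-type replicate 4 accounted for 9 of the 14. It was low for Cd38 (2.38 FPKM against 8.58 to 9.63 in the other wild-type libraries), Fscn1 (5.77 against 6.74 to 6.94), Psph (22.7 against 26.95 to 27.8) and Hspd1 (65.8 against 75.0 to 76.9). It was high for S100a8 (29.9 against 6.50 to 7.18), S100a9 (36.1 against 2.58 to 7.32) and Batf (61.9 against 31.2 to 35.01). Its mean log2 level was low for the sterol and fatty acid synthesis list (3.91 against 4.33 to 4.39) and the dark zone list (4.66 against 5.19 to 5.25). In the other libraries, S74C/+ replicate 1 was low for Cd38 (3.39 FPKM against 5.04 to 5.08), S74C/+ replicate 4 was low for Ccnd2 (2.60 against 3.72 to 3.86), and wild-type replicate 2 was low for Tpi1 (281.9 against 341.5 to 352.8). Wild-type replicate 1 was low for the mean log2 level of the Rag and mTORC1 list (3.85 against 3.91 to 3.92) and S74C/+ replicate 3 low for that of the T cell list (2.30 against 2.56 to 2.60).

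The higher glycolysis, MYC target, ribosomal protein and oxidative phosphorylation lists in S74C/+ were set against GC content and transcript length, since libraries differed along both, and after the correction the median of the glycolysis list was 0.2238 (0.2514 before) and that of the MYC target list 0.1444 (0.1333 before), both past camera's threshold with the preset correlation and beyond 2 standard errors, which argues against these trends as the whole cause of either. With an estimated correlation neither passed before the correction (adjusted p = 0.241 for each). The median of the ribosomal protein list was 0.0663 (0.1478 before), and its difference in mean went from 0.149 (SE 0.127) to 0.073 (SE 0.119), with the list still past camera's threshold with the preset correlation (adjusted p = 0.00176) and the difference within 2 standard errors of 0 before and after. That of the oxidative phosphorylation list was 0.0358 (0.0912 before), its difference went from 0.101 (SE 0.0885) to 0.033 (SE 0.0746), and its call ended because the difference shrank. For these 2 lists the trends stay open as a source of most of the difference, and for all 4 the genotype stays open and untested.

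The lower naive and memory B cell marker list in S74C/+ kept a median of -0.2455 after the same correction (-0.2066 before), beyond 2 standard errors, which argues against GC content and length as the whole cause. Fewer naive B cells carried through the CD38-negative gate would lower genes abundant in them. Of 6 such genes fixed in advance, Zfp318 did not reach the filter, and the median log2 fold change of Sell, Fcer2a, Cr2, Klf2 and Il6ra was -0.2066, where the bound was -0.2, and -0.2766 with Zfp318 included, which was under 1 FPKM in every library. These 5 genes are themselves members of the list and the value is that of Fcer2a (99.2 ± 29.9 FPKM in wild type and 82.2 ± 3.86 FPKM in S74C/+, SD, n = 4), which is also the median of the list, so it restates the pattern and supports nothing. A smaller share of naive cells and a lower level within the sorted cells, as a property of the genotype, cannot be told apart with these genes.

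The higher neutrophil and erythroid marker lists in S74C/+ were set against RNA of those cells, which the CD19 gate is meant to remove. The neutrophil genes moved together within genotypes, with a median pairwise correlation of 0.861, as RNA of neutrophils in some libraries would make them. For the erythroid genes the value was 0.437, between the bounds of 0.2 and 0.5, and for them RNA of red cell precursors and other causes cannot be told apart with 8 libraries. Of the 20 neutrophil genes measured 11 reached the filter, and of the 20 erythroid genes 13, with S100a8 at up to 256.1 FPKM and Hba-a1 at up to 1512 FPKM, both in S74C/+ libraries. Whether the genotype changed the share of such cells was not tested and stays open.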

How the results depend on the processing

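The GC correction, the GC and length correction, that correction with the title-run block, and the fits without the last title run and without S74C/+ replicates 2 and 4 were chosen after seeing the data. Where no cause is given, the cause was not tested. Xist was at most 0.0194 FPKM in every library and split none of them, so the fit with Xist as a covariate was not run. Depth is unknown from FPKM, so its limit on genes at low levels cannot be given.

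The count of genes higher in S74C/+ was 2, and it was 1 with no filter on low values, where more genes were tested, 1 with a mean of at least 5 FPKM, where Emp2 was not tested, 0 with the same total in each library, 63 with library weights, 0 with the GC correction, 0 with the GC and length correction, 1 with that correction and the title-run block, 11 without the last title run and 0 without S74C/+ replicates 2 and 4. The count of genes lower was 0, and it was 58 with library weights, 1 without the last title run and 1 without S74C/+ replicates 2 and 4. Leaving out 1 library gave 0 to 18 higher and 0 to 8 lower. The 14 lists called became 9 without S74C/+ replicates 2 and 4, 0 with an estimated correlation, 0 with fry and 9 to 19 with 1 library left out, the lowest without wild-type replicate 1 and the highest without wild-type replicate 4. Of the 77 genes followed through the settings, 75 had 1 direction in all, and of the 14 lists called 13 did, the exception being the G2 and M phase list. Most of these genes were picked by small p in the same libraries, and the lists by their call. Such agreement follows in part from that choice and is no separate support. The glycolysis, MYC target, interferon and naive B cell lists passed in 26 of 26 alternatives of camera with the preset correlation.

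The log2 fold change of Cd19 turned to -0.0478 with the same total, -0.0220 with quantile normalization and -0.0247 without S74C/+ replicates 2 and 4, and ran from -0.0412 to 0.2276 with 1 library left out. That of Vcam1 turned to 0.0113 with library weights. In 51 values over 8 lists the direction of the test turned, 2 of them past the threshold, both of the macrophage list. These are their adjusted p. With no filter it was 0.9992 for the S phase, light zone, apoptosis and class switching lists and 0.6716 for the macrophage list. With a mean of at least 5 FPKM it was 0.869 for S phase, 0.5899 for the light zone and 0.5315 for macrophages. With the same total it was 0.7409 for S phase and macrophages, and with quantile normalization 0.7586 for S phase and 0.8243 for the light zone. With library weights it was 0.2647 for S phase, 0.9732 for germinal centre identity, 0.7771 for apoptosis, 0.03029 for macrophages and 0.5955 for stromal markers. Without the last title run it was 0.4133 for S phase, 0.8267 for germinal centre identity, 0.7706 for apoptosis and 0.1693 for macrophages. Without S74C/+ replicates 2 and 4 it was 0.9819 for G2 and M phase and class switching. For the light zone it was 0.7513 with the title-run block, 0.8761 with the GC correction, 0.754 with the GC and length correction and 0.4739 with that and the block, and for apoptosis 0.9328 and 0.8653 with the last 2. With fry it was 0.9935 for S phase and class switching, and with ranks 0.9944 for macrophages. With 1 library left out, whichever the direction, it ran from 0.2657 to 0.9977 for S phase, 0.02101 to 0.9973 for the light zone, 0.4187 to 0.9699 for apoptosis, 0.8373 to 0.9977 for class switching, 0.02101 to 0.6822 for macrophages and 0.04419 to 0.8627 for stromal markers, with both values of 0.02101 without wild-type replicate 4.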

Other observations

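Of the tests here, the choice to repeat the splits without wild-type replicate 4 and with library weights was made because these settings called the most genes. The bound on the share of splits was set before each was run.

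Among the genes called with library weights, chosen here after their values were seen, Slc7a7, an amino acid transporter, was at 8.51 ± 2.30 FPKM in wild type and 14.2 ± 0.677 FPKM in S74C/+ (SD, n = 4, weighted adjusted p = 0.00574). Tifa, an adaptor of NF-kB signalling, was at 5.90 ± 1.70 and 2.42 ± 0.598 FPKM (weighted adjusted p = 0.0212), and Hes1, a Notch target, at 4.33 ± 0.899 and 7.70 ± 1.94 FPKM (weighted adjusted p = 0.0459). Without weights and with all 8 libraries their unadjusted limma p was 0.00140, 5.96e-04 and 0.00423, and none passed the adjustment. Slc7a7 also passed without wild-type replicate 4 (adjusted p = 0.0114) and without the last title run (adjusted p = 0.0233), a fit chosen after seeing the data, and Tifa without wild-type replicate 4 (adjusted p = 0.0473).

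The 2 genes past the threshold do not exceed what other splits of the libraries gave. Of the 35 splits of the 8 libraries into 4 and 4, 7 called as many genes, with 2 for the real split and up to 4 for the others, so chance is not excluded for this count. For the 14 lists called with the preset correlation, 1 of 35 splits, the real one, called as many, which is under the share of 0.05 set in advance, but by 1 list only, since 4 others called 13. Each of the other splits mixes the genotypes, and each called at least 1 list. A call with the preset correlation alone therefore does not point to genotype. Without wild-type replicate 4, 1 of the 35 splits of the 7 libraries called as many genes as the real one, with 26 against at most 3. With library weights, 1 of 35 splits called as many, with 121 against at most 17. These last 2 settings were picked for the size of their counts in the real split, so their shares do not exclude chance.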
